A study of Homo sapiens with 3 samples.

How the data were processed

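Human ProtoArray version 5.0 slides carry a large set of purified human proteins, each printed as a pair of adjacent spots. Per the labels' protocols, the slides were incubated with radioactive ATP and a recombinant LRRK2 fragment (50 nM, 33 nM ATP, 1 h at 30 °C) and exposed to a phosphorimager plate scanned at 50 microns. G2019S LRRK2, an active mutant form, was used on 2 arrays and D1994A LRRK2, a kinase-dead form, on 1 array. The labels' protocols also name slides with buffer alone, which were not analysed here. The labels give the start of the LRRK2 construct in different ways, so its length is not stated here.

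Spot intensity was read by the authors with Prospector Imager 5.2.1.0 and deposited without normalization, per the file headers. Each scanner file gave the pixel median and mean intensity of a spot and of the area around it for 23232 spots in 48 blocks of 22 rows and 22 columns. The deposited series table held a score whose scale, centring and direction are not stated and whose lines carry no protein name. The score had a median of -5.52 and -5.40 in the G2019S columns and -4.41 in the D1994A column, stayed below 1, and was not used here. Which G2019S column belongs to which array is unsettled.

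The median foreground was corrected for the local background with normexp (offset 50), put on the log2 scale, averaged over the 2 spots of a feature and quantile normalized between the arrays over 9480 human protein features. Control spots were left out after the correction. Plain foreground differences were computed in the same way without the background correction, so they are quantile normalized and depart from the ratio of the scanner readings. Of these features, 8302 had a gene symbol, 5273 of them through an accession in the supplied reference table and the others from the file's own descriptions with older symbols updated, for 7104 different symbols. The other 1178 features kept their accession or clone name. Features of one gene were kept apart, except that gene lists used the mean over a gene's features. A feature was above background where its corrected signal exceeded the mean plus 2 SD of 594 buffer, empty and albumin spots of the array. The array's highest foreground value was taken as its ceiling, and a feature was at the ceiling (saturated) where at least 1 of its 2 spots reached 95% of it. Fold bounds set the mean of the group above background against the higher of the dim feature's own value and the lowest value above background on the same array, in normalized log2 units. Where the feature's own value was the higher on each array, the fold is the fitted one and not a bound. No fold is given for a feature saturated on D1994A 1, or for a feature below background in both groups.

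Groups were compared with limma's lmFit and eBayes (two-sided, Benjamini-Hochberg adjustment at 0.05), with 1 residual degree of freedom per feature and 3.08 after moderation. The lone D1994A array was assumed to vary like the G2019S arrays. The labels do not say whether the arrays used separate kinase preparations, so a p value measures only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value. A description without a test followed the usual reading of kinase arrays: a feature met the candidate rule with a Z-score of at least 3 on both G2019S arrays and a normalized log2 difference from D1994A of at least 1 on each of them. A feature was bright on an array with a Z-score of at least 3. Kinase genes among the genes bright on each array, and on all arrays, were tested with Fisher's exact test (two-sided, 4 comparisons, Benjamini-Hochberg), with each feature lacking a symbol counted as a gene of its own.

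Of the 18 gene lists tested, 1 is not reported. The others were tyrosine, AGC, CAMK, CMGC, STE, and TKL and CK1 kinases, reported LRRK2 substrates and partners, Rab GTPases, 14-3-3 proteins, cytosolic ribosomal proteins, translation factors, tubulins and microtubule proteins, actin cytoskeleton and ERM proteins, histones and HMG proteins, SR and splicing proteins, and proteasome subunits and cytokines and chemokines as comparators. The 6 kinase lists together held 614 features of 293 genes. Lists were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists) and set against 10000 random lists of the same size matched on mean signal. Proteins named were the 15 past adjusted p with the largest difference (there were none), the 15 features meeting the candidate rule with the largest smaller difference, the 5 features above background on D1994A lowest with G2019S, LRRK2, up to 4 members per list with the largest difference, and the 5 brightest features with each LRRK2 form. Any protein named outside this rule is marked as chosen after its values were seen.

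On data simulated from these arrays for the G2019S against D1994A comparison (9480 features), limma called 0 of 67 features changed by 1 on the log2 scale, 0 of 67 changed by 2, and 39 of 66 changed by 4, with 1 of 9280 unchanged features called. Estimated changes averaged 0.96, 1.80 and 3.73. Of the raised features, 38.2%, 97.0% and 100% lay at least 1 above D1994A on both G2019S arrays. A simulated shift of 0.5 in the 52 CMGC kinases was called by camera and 0 other lists were. The single-feature changes were placed outside the brightest features. Both simulations used noise independent between features, with no ceiling, light from neighbouring spots or print lot. They therefore do not show how the tests or the rule perform on bright or saturated features.

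The deposited spot names show 2 print lots: G2019S 1 and D1994A 1 share a lot and G2019S 2 is from the other. The value within the shared lot is therefore the G2019S 1 against D1994A 1 difference, and a fit with the lot as a term leaves no residual degree of freedom and gives the same difference. Alternatives covered the background correction, normalization, foreground column, duplicate spots, the eBayes trend, Z-score and difference limits, the correlation in camera, and each G2019S array left out. These choices, the candidate rule, the limma and camera tests and the lists were fixed before the data were examined, and 5 alternatives were added afterwards. Bright features were planned as a description with no test, to which the Fisher's exact tests of kinase genes were added. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.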

Results

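Phosphate incorporation into 9480 human protein features was measured on 3 protein microarrays, 2 incubated with active G2019S LRRK2 and 1 with kinase-dead D1994A LRRK2, to find substrates of the Parkinson's disease kinase LRRK2. The arrays differed in how far their images reached the top of the scale. The highest foreground was 65535 scanner units on both G2019S arrays and 58259 on D1994A 1. It was shared by 239 spots on G2019S 1, 11 on G2019S 2 and 246 on D1994A 1, and the features at the ceiling numbered 101, 19 and 178. The files do not say whether the D1994A image was rescaled or scanned over another range, so its scanner units and its ceiling are not known to be on the scale of the G2019S arrays. The spots on D1994A 1 that read 0 numbered 669, against 0 on either G2019S array. Protein kinase C eta, a control kinase printed in every block, had a median foreground of 63607 on G2019S 1, 11400 on G2019S 2 and 58143 on D1994A 1. Features above background numbered 393 on G2019S 1, 207 on G2019S 2 and 436 on D1994A 1. Among these, the duplicate spots differed with an SD of 1.23, 1.33 and 1.10 on the log2 scale in the same order. Over all features the SD was 0.44, 0.42 and 0.46.

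Without background correction, printed protein kinases were common among the strongest signals on every array, with kinase-dead LRRK2 as with active LRRK2. They made up 60.3%, 68.8% and 59.5% of the genes in the top 1% of foreground on G2019S 1, G2019S 2 and D1994A 1, and 68 of the 151 genes (45.0%) at the ceiling of D1994A 1. Of the 53 features in the top 1% on all 3 arrays, 41 were kinases of the lists, and of the 42 with no brighter spot beside them, 39 were. The rest of the 42, BC020972 (casein kinase I gamma-2), TLK2 and TBK1, are protein kinases too. They are outside the lists and count among the other genes below. The kinases among these 42 included protein kinase C isoforms (PRKCA, PRKCB, PRKCD, PRKCI, PRKCQ and PRKCZ), the tyrosine kinases EGFR, SYK, ABL1 and MET, the Hippo pathway kinases STK3 and STK4, the checkpoint kinase CHEK1 and the casein kinases CSNK1G1 and CSNK1G2. These proteins were chosen after their values were seen. All 42 features were saturated on both G2019S 1 and D1994A 1, so their signals there cannot be ranked or compared. The top 1% on D1994A 1 began at 57694, above the limit of 55346 for saturation. CHEK1 read 65535 on both G2019S arrays and 58259 on D1994A 1. Its local background equalled its foreground on G2019S 1 and D1994A 1, as it did for PRKCD and for a SYK feature.

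After background correction, 248 features were bright with D1994A, and G2019S 1 shared 173 of them (6.51 for independent lists) and G2019S 2 shared 87 (5.00 for independent lists). All 3 arrays shared 69 bright features, 26 of them kinases, and 57 were bright with D1994A alone. Of 293 kinase genes, 69 (23.5%) were bright on D1994A 1, 73 (24.9%) on G2019S 1 and 86 (29.4%) on G2019S 2. Odds ratios against other genes were 14.1, 16.4 and 38.1 in the same order (Fisher's exact test, adjusted p 3.66e-45, 5.16e-51 and 3.62e-81). The 24 kinase genes bright on all arrays gave an odds ratio of 16.5 (adjusted p 1.44e-18, Fisher's exact test). Kinase genes had more features than other genes, and counted by feature the odds ratios were lower, at 6.99, 9.40 and 20.5, and 9.07 on all arrays. Proteins are not independent replicates, and these p values describe the printed proteins. After background correction a saturated feature can fall short of bright. Of the 42 saturated features above, PRKCB had the highest Z-score on D1994A 1, at 2.06. G2019S 2 had the fewest features at the ceiling (19, against 101 on G2019S 1 and 178 on D1994A 1). The shares and odds ratios therefore cannot be compared between arrays.

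**Figure D1:**
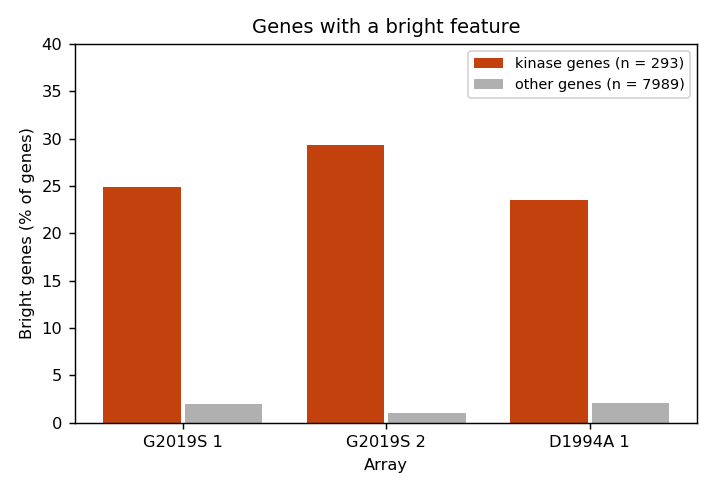
Share of genes with a bright feature (percent of genes, y axis) on each array (x axis), for 293 kinase genes and for other genes. Kinase genes stood at 24.9%, 29.4% and 23.5% on G2019S 1, G2019S 2 and D1994A 1. Saturated features can fall short of bright, so the shares cannot be compared between arrays.

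The highest corrected signals on D1994A 1 belonged to LINC00312, the methionine adenosyltransferase MAT1A, the chemokine CCL3, the secreted protein EGFL7 and the mitochondrial protein prohibitin 2 (PHB2). With G2019S they belonged to the extracellular matrix protein ECM1, the recombination protein RAD51D, the natural killer cell receptor KLRD1, the spindle checkpoint protein MAD2L1BP and LINC00312. Each of these features had a brighter spot of another protein beside it on both G2019S arrays. LINC00312 read 51207, 21043 and 55330 scanner units on G2019S 1, G2019S 2 and D1994A 1, and RAD51D read 59688, 36222 and 52718. Among features bright on D1994A 1, 164 of 173 outside the kinase lists had a brighter neighbour, against 22 of 75 kinase features. Over all features on that array the share was 92.7%.

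No protein passed the test of G2019S against D1994A. By limma, 0 features passed an adjusted p of 0.05, the smallest adjusted p was 0.738, and 346 features had an unadjusted p under 0.05 (150 higher and 196 lower with G2019S), where chance alone would give 474. LRRK2 itself, printed as 2 features, was not well above background on any array. It read 17348 and 32768 scanner units on G2019S 1, 9260 and 17495 on G2019S 2, and 23783 and 42047 on D1994A 1.

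The candidate rule was met by 33 features, 18 of them kinases of the lists, and by 1 of these 33 without background correction. Of these, 30 were at the ceiling of D1994A 1 and 22 were at the ceiling of G2019S 1. They included ECM1, the stress kinase MAPK10, MAD2L1BP, the nucleoside diphosphate kinase NME1, the casein kinases BC020972 (casein kinase I gamma-2), CSNK1G2 (on 2 features) and BC011668 (casein kinase II alpha), PRKCZ, ABL1, the splicing kinase CLK3, the microtubule-associated kinase MARK4 and the receptor kinase MET. All of these were saturated on D1994A 1, so no fold is given. The local background of the 30 saturated features stood at 92.8% of the foreground on D1994A 1, against 78.3% on G2019S 1 and 73.1% on G2019S 2. Of the 110 features bright on both G2019S arrays, 51 were at the D1994A ceiling and 30 of these met the rule, while 3 of the 59 below the ceiling met it.

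**Figure D2:**
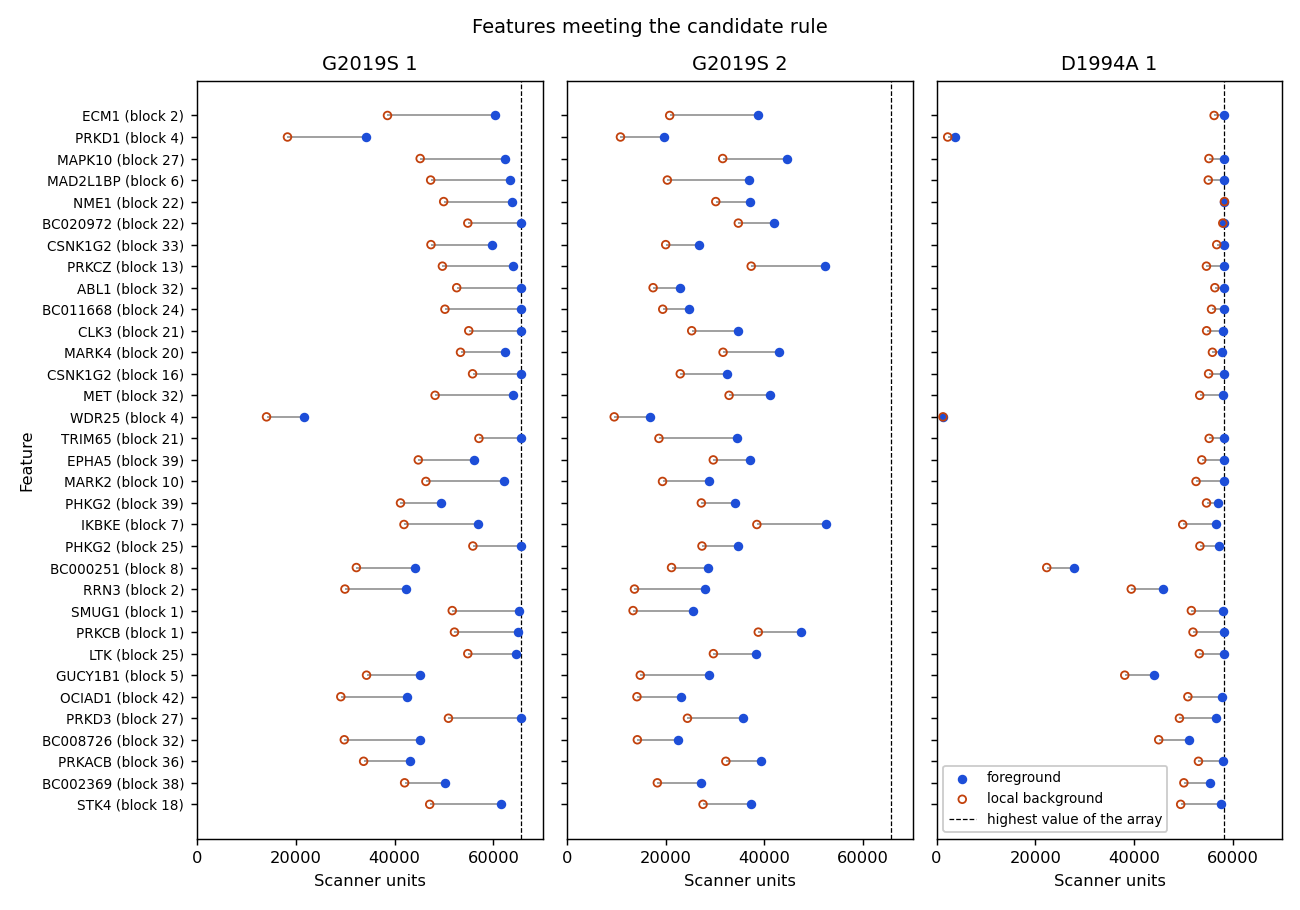
Foreground (filled points) and local background (open points) in scanner units (x axis) of the 33 features that met the candidate rule (y axis), on each array. On D1994A 1, 30 of them had a spot at or near its highest value of 58259, with a local background close to the foreground.

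The 3 features below the D1994A ceiling were the serine/threonine kinase PRKD1, the WD repeat protein WDR25 and BC000251, a clone of the Wnt and insulin pathway kinase glycogen synthase kinase-3 beta. None was well above background on D1994A 1. PRKD1 (block 4) was at least 5.31-fold brighter with G2019S (log2 13.45 against 10.52, SE of the difference 0.21, adjusted p 0.919), and WDR25 (block 4) at least 2.40-fold (log2 12.30 against 10.26, SE 0.36, adjusted p 0.998). Both lay beside a brighter control spot, and D1994A 1 was dim there: its local background in block 4 was 2600 scanner units (9076 over the array) and the control kinase 49419. A GST1 control pair touching both features read 0 on D1994A 1, with a local background of 0. Block 3 was dim on D1994A 1 as well (3216 and 49279). BC000251 had no brighter neighbour and was 2.52-fold brighter as fitted, which is not a lower bound (log2 13.04 against 11.71, SE 0.14, limma adjusted p 0.998). The difference was 1.31 on G2019S 1, the array of the same print lot, and 1.36 on G2019S 2. It was chosen after its values were seen, as was PRKCH below. In scanner units BC000251 read 44075, 28570 and 27729 on G2019S 1, G2019S 2 and D1994A 1. The 3 other features of the gene, printed as GSK3B, read in the same array order 8803, 866 and 16649, then 17284, 16494 and 23851, and last 31548, 32183 and 51015. The second lay 0.34 above D1994A 1 on G2019S 1 and 1.08 on G2019S 2 in normalized log2 units, without being above background on any array. The last, the only one above background on D1994A 1, lay at -0.57 on G2019S 1 and 0.44 on G2019S 2. The other PRKD1 feature was saturated on D1994A 1. In plain foreground, which was quantile normalized without background correction, 2 features met the rule, BC000251 and PRKCH (protein kinase C eta, block 3), which read 65535, 38312 and 29845. Before normalization the log2 difference was 0.67 on G2019S 1 and 0.04 on G2019S 2 for BC000251. For PRKCH it was at least 1.13 on G2019S 1, where the feature was saturated, and 0.36 on G2019S 2. A further PRKCH feature was saturated on D1994A 1. The control kinase spots of block 3, which also hold protein kinase C eta, went the other way on G2019S 2. Their median was 64250 on G2019S 1, 10916.5 on G2019S 2 and 49279 on D1994A 1.

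**Figure D3:**
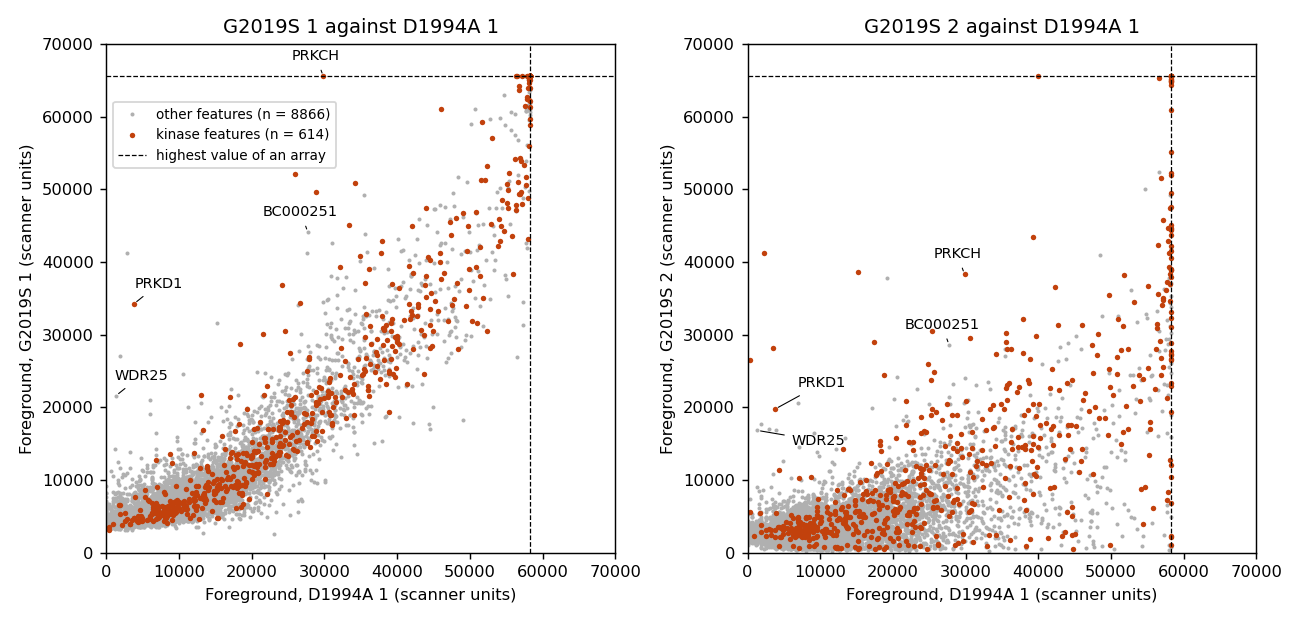
Foreground in scanner units of each feature on D1994A 1 (x axis) against G2019S 1 and G2019S 2 (y axes), with kinase features coloured and the highest value of each array dashed. BC000251 lay at 27729 on D1994A 1 and at 44075 and 28570 on the G2019S arrays.

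Other proteins were brighter with D1994A. The features above background on D1994A 1 that lay lowest with G2019S were the endoplasmic reticulum protease ERMP1, the Down syndrome region kinase DYRK1A, the chemokine CXCL10, the calcium-binding protein S100A3 and the nucleoside diphosphate kinase NME3. ERMP1 was at least 2.16-fold brighter with D1994A, DYRK1A at least 2.85-fold, CXCL10 at least 2.81-fold and NME3 at least 2.61-fold. S100A3 was 3.28-fold brighter as fitted, which is not a bound. The adjusted p of limma was 0.998 for each. Both DYRK1A features lay in block 37, 1 of the 3 blocks where the control kinase read far below its median on G2019S 2 (4626 scanner units in block 37). All of these folds come from background-corrected values. In plain foreground, quantile normalized, the log2 difference on G2019S 1 and G2019S 2 was -1.28 and -0.79 for ERMP1, -0.20 and -4.07 for the DYRK1A feature lowest with G2019S, -0.99 and -0.59 for CXCL10, -0.94 and 0.31 for S100A3, and -0.55 and -0.63 for NME3. Before normalization all of them were lower on both G2019S arrays, with S100A3 at -1.33 and -0.95. The median foreground of all features was also lower there, at 6361.5 on G2019S 1 and 3230 on G2019S 2 against 9338 on D1994A 1. A lower value before normalization is therefore not particular to these features. Outside DYRK1A and NME3, each had a brighter spot beside it.

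G2019S 1 followed D1994A 1, from the same print lot, more closely than it followed G2019S 2. Across features, which are not independent replicates, Spearman's rho was 0.855 (Pearson's r 0.899) for the former and 0.741 (0.783) for the latter, with the SD of the log2 difference at 0.29 and 0.43. With cyclic loess normalization the order turned, at 0.828 and 0.849. G2019S 2 and D1994A 1 stood at 0.698 (0.719) with quantile normalization. Over features above background on either array, the G2019S arrays had a rho of -0.01 and G2019S 1 and D1994A 1 had one of 0.450. The G2019S arrays shared 110 bright features (5.02 for independent lists). Within the shared lot, 54 features met the candidate rule on G2019S 1 alone, against 95 on G2019S 2 alone.

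Of the 18 gene lists, the AGC kinases were higher with G2019S. Their 48 genes had a median log2 difference of 0.16 (mean 0.25, camera p 0.000928, adjusted p 0.0167, at the 99.9th percentile of random lists), and 24 of them were higher on both G2019S arrays and 7 lower. With an estimated correlation the adjusted p was 0.776 (p 0.365), and all 18 lists had an adjusted p of at least 0.776. Within the shared print lot the median was 0.03, and on G2019S 2 it was 0.28. The AGC members furthest apart included PRKCH, PRKCZ and PRKCQ, each with a feature saturated on D1994A 1. Without features at the D1994A ceiling the adjusted p was 0.519 and the median 0.04. In plain foreground the adjusted p was 0.943 and the median 0.12 (0.15 without features at the ceiling).

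The other kinase lists were not called, and the members named for each list are those with its largest differences. Tyrosine kinases had a median of 0.14 (adjusted p 0.0682), led by JAK3, ROS1, EPHA5 and TYRO3, all saturated on D1994A 1. CAMK kinases had 0.06 (0.162), with PRKD1, DAPK3, PHKG2 and MARK4, and CMGC kinases 0.03 (0.162), with DYRK1A, SRPK2, MAPK10 and CLK4. STE kinases had -0.02 (0.939), with PAK5, STK4, MAP2K2 and PAK3, and a mean of 0.10 that differed in sign. TKL and CK1 kinases had 0.03 (0.562), with CSNK1G2, TTBK2, CSNK1G1 and IRAK3. Over all features 0 list members passed limma's adjusted p. Adjusted over the list alone, 2 tyrosine kinase features (ABL1 and JAK3, adjusted p 0.0444 for both), 1 CMGC kinase feature (MAPK10, 0.0301) and 1 TKL and CK1 feature (CSNK1G2, 0.0215) passed, each saturated on D1994A 1, and 0 features of any other list did.

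Lists linked to LRRK2 were not called, and most of their members were not above background on any array. The 34 reported LRRK2 substrates and partners had a median of -0.07 (adjusted p 0.562, at percentile 4.51 of random lists), and 7 of them were above background on any array. The members furthest apart were CDK5, BAG5, RAB35 and MAP2K6. The 39 Rab GTPases, the family best known as LRRK2 substrates in cells, had -0.04 (0.254), with RAB28 the 1 member above background. RAB4A, RAB35 and RAB40B were not well above background on any array. The 3 printed 14-3-3 proteins (YWHAB, SFN and YWHAZ) stood at 0.16 (0.937), where camera pointed down, and none of them was above background on any array.

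The remaining lists were not called either. Cytosolic ribosomal proteins had a median of 0.09 (adjusted p 0.196), with RPS18, RPLP2, RPS27L and RPL31, and translation factors -0.03 (0.895), with EIF4E, EIF1, EIF3E and EIF2B3. Tubulins and microtubule proteins had 0.01 (0.592), with MAPRE2, TBCC, NUSAP1 and TBCD, and actin cytoskeleton and ERM proteins 0.03 (0.561), with TAGLN3, ACTR3, ARPC1B and PLS3. Histones and HMG proteins had 0.08 (0.0682), with HMGN3, H2AC13, H2BC9 and HMGN2, and SR and splicing proteins 0.08 (0.162), with SRSF8, SRSF9, SRSF1 and AKAP17A. The comparators were proteasome subunits at 0.07 (0.592), with PSMA6, PSMA3, PSMD11 and PSMB8, and cytokines and chemokines at -0.04 (0.196), with CXCL10, IL1A, CXCL2 and IL1B.

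**Figure D4:**
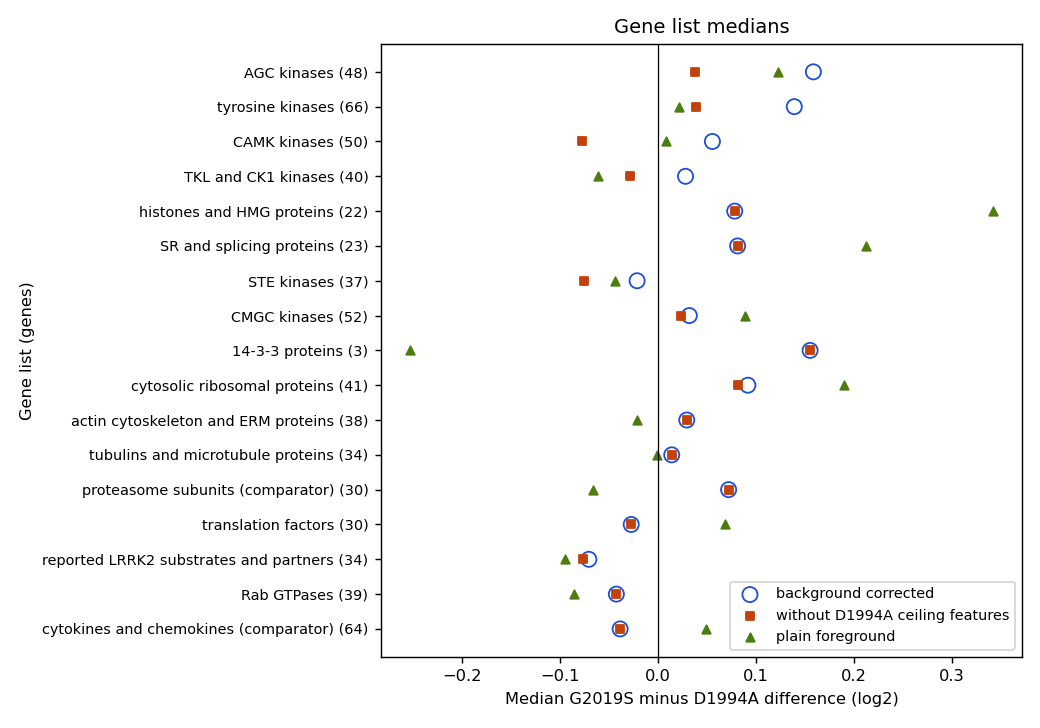
Median log2 difference between G2019S and D1994A (x axis) of each gene list reported (y axis, number of genes in brackets), background corrected, without features at the D1994A ceiling, and in plain foreground. The AGC kinase median was 0.16 with the background correction and 0.04 without the features at the ceiling.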

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

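The tests of the D1994A ceiling, of IGLC1, of the other GSK3B features, of the dim blocks and of spots beside bright kinases were chosen after the results were seen.

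A control pair left out of the comparisons was bright with active LRRK2 and dim with kinase-dead LRRK2. The pair is named Internal_1700 (block 4), and the files do not say what protein it holds. It read 65535 scanner units on G2019S 1, 51215 on G2019S 2 and 7506 on D1994A 1, a log2 difference of at least 3.13 on G2019S 1, where it was saturated, and of 2.77 on G2019S 2. Quantile normalized without background correction (plain foreground), the differences were 3.48 and 3.55. Block 4 was dim on D1994A 1, with a local background of 2600 against 9076 over the array. A GST1 control pair diagonal to Internal_1700 read 0 on D1994A 1, with a local background of 0. It read 10280.5 on G2019S 1 and 7547 on G2019S 2. Whether this dim region accounts for the Internal_1700 pair was not tested. Of 1836 control pairs it was the 1 pair that met the candidate rule in plain foreground. With background correction 11 control pairs met the rule, 2 of them below the D1994A ceiling, and both of these had a brighter neighbour. A second pair of the same name (block 11) was dim on every array, at 6233, 3392 and 8620. With background correction the first pair did not meet the rule, since its local background on G2019S 1 was 61359.

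Most proteins that met the candidate rule were saturated on D1994A 1: of the features bright on both G2019S arrays, 58.8% at its ceiling met the rule and 5.08% below it (odds ratio 25.7), a contrast that the saturated values fix. For the 30 saturated proteins the ceiling and LRRK2 kinase activity cannot be told apart, since a test between the G2019S arrays was not decisive either: 69 features at the G2019S 1 ceiling lay -0.17 from 102 features below it (permutation p 0.236). For WDR25, the spot nearer to the bright Internal_1700 pair exceeded the farther one by at least 1.58 on both G2019S arrays. Light from that neighbour would give such a difference. On D1994A 1, where the pair read 7506, the nearer spot read 2600 and the farther 0. The foreground of WDR25 there equalled its local background, both at 1300, so no such difference can be read on that array. Whether light from the pair also reached PRKD1 is undecided: IGLC1, on the other side of the pair and chosen after its values were seen, differed in quantile-normalized plain foreground by 3.71 and 3.43, against 3.22 and 3.38 for PRKD1, but with background correction by -1.55 and -1.63, against 3.08 and 2.76. LRRK2 kinase activity as the cause stays open for BC000251 and, without a test, for PRKD1: 0 of the 3 other GSK3B features were higher by 1 on both G2019S arrays, but 2 of those 3 were not above background on any array.

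G2019S 1 lay closer to D1994A 1 than to G2019S 2, except with cyclic loess, where rho was 0.849 between the G2019S arrays. Unequal amounts of printed protein in the print lots were tested across 9150 features. The lot ratio of printed amount had a rho of 0.0268 with the G2019S 1 minus G2019S 2 difference (95% bootstrap interval 0.00591 to 0.0478). Most of these features were not above background on any array, where the printed amount could hardly show. Over the 497 features above background on at least 1 array the rho was 0.0293, with no interval computed. The printed amount is therefore undecided for features with signal. Blocks with dim control spots do not account for the closeness of G2019S 1 to D1994A 1. Without 3 such blocks the correlation with D1994A 1 was still higher by 0.0935 (0.0813 to 0.105). Another property of the lot, or the wide gap in exposure between the images, may be the source and was not tested. No biological explanation was tested, as the pattern runs across the groups.

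Kinases were bright with kinase-dead LRRK2 more often than other proteins. Matched on the amount of printed protein, kinase features were bright on D1994A 1 5.38 times as often as others (95% bootstrap interval 3.90 to 7.36), which argues against the amount as the whole cause. Light from brighter spots nearby is argued against only for the bright kinase features without a brighter neighbour. Below the ceiling, 20 of 62 bright kinase features had one and 156 of 163 other bright features did (odds ratio 0.0220, Fisher's exact test p 4.78e-23). For those 20 such light stays possible. The test repeats most of the contrast already seen on D1994A 1 (22 of 75 against 164 of 173), so its p value adds no independent support. The printed kinases labelling themselves from the radioactive ATP is a possible explanation that these arrays could not test, since slides with buffer alone were not analysed here.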

How the results depend on the processing

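The settings that left out D1994A ceiling features, features beside brighter spots or dim blocks, and block centring, were chosen after the data were seen; the others were planned. No paired analysis was possible because the groups share only replicate number 1. The deposited score table was planned as an alternative and not run, since its lines carry no names and no log-scale intensity.

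The count of 0 proteins past limma's adjusted p held in 14 of 16 settings. Subtracted local background with a floor gave 412 (48 higher, 364 lower), 341 of them with both G2019S arrays at the floor. Duplicate spots kept apart, where the spots of 1 array stand in as replicates (duplicate correlation -0.0431), gave 3: ECM1 and KPTN, both saturated on D1994A 1, and PRKD1, named after their values were seen. Unadjusted p under 0.05 ranged from 5 to 1186 features.

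With the mean foreground column 26 features met the candidate rule, 14 of them among the 33 of the main setting, and with cyclic loess 22 met it. The 33 features of the candidate rule became 2 with no background correction (1 of the 33), 19 with no normalization, 1 with scaling on the control kinase spots (ECM1) and 52 with a robust Z-score. They became 3 without D1994A ceiling features, 1 without brighter-neighbour features too (BC000251), and 2 in plain foreground without ceiling features. Leaving out each G2019S array gave 54 to 95. No normalization and control scaling moved the median of all features by -0.47 and -1.16. Control scaling rests on spots whose median was above the saturation limit on G2019S 1 (63607) and D1994A 1 (58143). On G2019S 2 their median was 11400, so values with control scaling are of limited use. BC000251 stayed above 0 in every setting, from 0.30 with control scaling to 1.48 with median centring. Features bright with D1994A, 248, became 391 at a Z-score of 2, 46 without ceiling and brighter-neighbour features and 105 in plain foreground without ceiling features.

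The rho of the G2019S arrays, 0.741, became 0.555 with no background correction, 0.662 with subtraction, 0.849 with cyclic loess, 0.171 over features above background, 0.535 in plain foreground without ceiling features and 0.762 without dim blocks. The duplicate spot spread on G2019S 1, G2019S 2 and D1994A 1 became 0.60, 0.61 and 0.44 with no background correction, and 2.58, 2.36 and 2.42 with subtraction. It became 0.49, 0.30 and 0.33 without ceiling and brighter-neighbour features, and 0.57, 0.57 and 0.46 in plain foreground without ceiling features. With mean foreground it was 1.01 on D1994A 1.

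The AGC kinase list (camera adjusted p 0.0167) was not called with no background correction (0.943), subtraction (0.789), median centring (0.817), mean foreground (0.226), estimated correlation (0.776) or each feature counted (0.132). Nor was it without ceiling features (0.519), or in plain foreground without them (0.690). Without ceiling and brighter-neighbour features the call was lost too (0.800) and the direction in camera turned, with the median at 0.13 over 17 genes. In its other settings the adjusted p lay between 0.000379 and 0.0187. These include no normalization and control scaling, where the AGC median was -0.37 and -1.05, lower with G2019S. Camera sets a list against the other features, so any list call in these settings is relative to them. Tyrosine kinases were called with no normalization (0.000379), control scaling (0.000379), features above background (0.00156) and without dim blocks (0.0154). CAMK kinases were called in the first 3 of these (0.000379, 0.000379 and 0.00431), and TKL and CK1 kinases with no normalization (0.0155) and control scaling (0.0155). Histones and HMG proteins were called with subtraction (0.0372), cyclic loess (0.0164) and mean foreground (0.00323), and cytokines, downwards, over features above background (0.0289). The lists called numbered 4 with no normalization, control scaling and features above background, 2 with cyclic loess and without dim blocks, and 0 with no background correction, median centring, estimated correlation, each feature counted, and the 3 settings without ceiling features. All other list calls, 261 of 283, held their side of the threshold, and 38 list directions turned. Some lists had no members left over features above background (2 lists) or without ceiling and brighter-neighbour features (3 lists). Except for the floored calls, the cause was not tested.

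Signal over background limits these arrays: 557 of 9480 features were above background on at least 1 array.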
